A study of Mus musculus with 8 samples.

How the data were processed

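Liver RNA was measured in pools from pregnant mice and their male fetuses, each pool drawn from mothers with free access to food or from mothers on 50% food restriction (FR). Per the labels, 1000 ng of RNA per pool was dye-labelled and a control pool and an FR pool shared each array, once in each dye orientation, on 2 slides of the Agilent mouse 44K design. The titles, with pool sizes from the descriptions, put the 8 arrays in 3 groups: mothers, pools of 6 animals (1 pool pair, 2 arrays); fetuses, pools of 6 (1 pool pair, 2 arrays); and fetuses, pools of 3 (2 pool pairs, 4 arrays). The control and FR pools of an array were compared within it. The descriptions of the arrays also mention rat hippocampus and exercise, which was read as text left from another study. The same text calls the dye-exchanged arrays Pool 2, against the titles and source names, which give both arrays of an exchange the same pool. The titles were followed, and the number of pool pairs rests on that reading. Sex and fetal marker genes were used to check the labels. Xist had a log2 level of 13.0 in control mothers and 6.54 in the control fetal pools of 6, the Y-linked gene Ddx3y had 6.16 and 11.3, and Afp 7.85 and 17.0.

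Per the file headers, the scanner files hold intensity values for Cy3 and Cy5, spot and local background, from Agilent Feature Extraction. The submitters' processing notes name version 9.5.3.1, which the headers give for slide 1, while the headers of slide 2 give a later version. The deposited values are log10 ratios of Cy5 over Cy3. How the authors made them is not stated in the labels, but they matched log10 of the processed red over green signals of the scanner files, with a largest difference of 5e-08. The medians of the deposited log10 ratios per array ranged from -0.0184 to 0.0155. The deposited values are not turned for the dye exchange. Flags of 0 or 1 per spot came with the files.

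The scanner files were read with R 4.3.3, data.table (version 1.17.8) and jsonlite 2.0.0, and analysed with limma 3.58.1, with statmod 1.5.0 for random blocks. Spot signal was the mean on slide 1 and the median on slide 2, whose files lack the mean. Background was corrected with normexp (offset 50), and each array was normalized by loess with control spots at weight 0. The values computed here are log2 ratios, where the deposited ones are log10, and all were turned to FR minus control. Control spots and spots marked as non-uniform or as population outliers were left out, saturated spots were kept, and spots of the same probe were averaged. A probe was kept if it was well above background for 1 diet on every array entering the result. Each gene was read from the probe with the highest mean intensity over all arrays among those that passed. Of 41174 probes, 26918 were named by accession, 5082 by symbol and 817 by an older symbol. The other 8357 could not be matched to a gene. They kept the gene name of the array or the probe name, and count as genes in the totals where they passed the filters. Probe coordinates are those of the slide 1 annotation (mm9). Median intensities, and the 25468 probes well above background throughout, set what the arrays could measure.

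The 2 arrays of a pool pair were averaged to 1 replicate. Fetal genes were tested with limma (lmFit and eBayes against 0, Benjamini-Hochberg adjustment) on the 2 pairs of pools of 3, and on all 3 pool pairs. Maternal genes were selected by a 2-fold change on both arrays. The maternal minus fetal difference was tested with limma on group means, where the lone maternal pair was assumed to vary like the fetal pairs. Control levels of mothers and fetuses were compared with single-channel values after quantile normalization of mean intensity (Aquantile). Fetal gene lists were tested with camera (preset correlation 0.01) and the limma function fry, and maternal list medians were ranked among 10000 random lists of the same size matched on intensity in 20 bins (2000 in the alternatives), with a seed of 1. The 27 lists, the comparisons, tests, thresholds, alternative settings and the rule for naming genes were fixed before the data were examined.

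The rule named the 10 highest and 10 lowest fetal genes among those past the threshold in the pools of 3 with the same sign on all 6 arrays, or, where none passed, by size among genes of at least 1.5-fold. It further named the 10 maternal genes highest and lowest among those over 2-fold on both arrays, the 5 largest opposite differences each way, the 5 largest level differences each way, up to 4 members of each list by size per comparison, and Trib1, Lepr, Igf1, Igf2, Igfbp1, Afp, Alb, Pck1, Cyp7a1, Fkbp5 and Tsc22d3 in any case. Clone and accession names were left out, and some genes that the rule named are not reported here. The 5 lists of interferon-stimulated, leukocyte, heat shock factor, cold-inducible and chaperonin genes were written after the data were seen.

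The settings varied were another normexp offset (10), no loess, scaling between arrays, the processed signals, the deposited table, other filters on dim probes, the mean of all probes, trend and robust priors, other thresholds, single dye orientations, other sets of pool pairs, unpaired single-channel values and other list tests. Keeping non-uniform spots, median signals on all arrays, the slide as a random block with a set correlation of 0.5, and adjustment over genes measured in both comparisons were chosen after seeing the data. Random blocks took their correlation from a fit without the dye term, since the fit with it gave no estimate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

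The steps were tested on simulated data. In these, all pools varied independently, the maternal pool varied like the fetal ones and no spot was marked as non-uniform. The shares below hold only under those assumptions, which the real arrays may not meet. Few genes were changed, namely 67, 67 and 66 at 1.5-fold, 2-fold and 4-fold in the pools of 3. There the smallest limma adjusted p was 0.00177, against 0.0515 in the real pools of 3, where 0 genes passed 0.05. The shares for the pools of 3 therefore do not describe that real fit. In the pools of 3 (24060 genes), 10.4% of genes simulated at 1.5-fold, 88.1% at 2-fold and 100% at 4-fold were recovered with the right sign, and 22 of 154 calls were unchanged genes. With all 3 pool pairs (23506 genes) the shares were 77.6%, 98.5% and 100%, with 17 unchanged genes among 201 calls. The maternal 2-fold rule (25143 genes) recovered 2.99% at 1.5-fold, 41.8% at 2-fold and 99.4% at 4-fold, and 58 of 253 genes it selected were unchanged. The test of the difference with all 3 fetal pairs (23188 genes) recovered 90% of 100 genes raised 4-fold in the mother alone and called 7 others. Camera called a simulated list of raised genes at a p under 0.05 and did not call a simulated unchanged list.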

Results

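Gene expression was measured in liver of pregnant C57BL/6J mice and of their male fetuses after the mothers were fed 50% of the food eaten by controls (food restriction, FR) from gestation day 10 to 17. Livers were taken on gestation day 18 from 6 mothers per diet and 2 male fetuses per mother. RNA was pooled within each diet, and an FR pool and a control pool were hybridized to the same Agilent 2-colour array, then again with the dyes exchanged. There were 8 arrays on 2 slides. Slide 1 held the maternal pools of 6 animals (2 arrays) and the fetal pools of 6 (2 arrays), and slide 2 held 2 separate pairs of fetal pools of 3 (4 arrays). The titles and source names give both arrays of a dye exchange the same pool, while a description text that also names rat tissue calls the exchanged array Pool 2. The titles were followed, and if the pools differed, the number of replicates and every SD would have another meaning. The number of arrays limits the precision of every value. Of 41174 probes, 25468 were well above background in both channels of all 8 arrays. Median raw signals per array ranged from 70 to 284 in Cy3 and from 122 to 310 in Cy5, over background medians between 46 and 68.

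All values are log2 ratios of FR over control. Fetal values are means ± SD over the 3 pool pairs (n = 3), with limma adjusted p-values from the fit of all 3 pairs. Spots on slide 1 that the image software marked as non-uniform in Cy3, which included 83.8% to 91.4% of the brightest 10% of spots per array, were kept for these gene values and for the counts of list genes in the 3-pair fit, a choice made after seeing the data. Every gene named as risen or fallen had the same sign in all 3 pool pairs. The 12 fetuses per diet in these pools equal the 2 fetuses of each of 6 mothers, but the labels do not say which mothers contributed to which pool. Pools may therefore share mothers or RNA, and the p-values of the 3-pair fit may be too small. Maternal values are means of 1 dye-swap pair of 1 pool per diet, so they have no replicate and no test of their own. Where limma p-values involve them, the spread is that of the fetal pairs, and the maternal spread was not measured.

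The first comparison asked which fetal liver genes responded to maternal FR. Genes that glucocorticoids and fasting induce rose in fetal liver, led by the tyrosine-degrading enzyme Tat at 2.05 ± 0.32 (adjusted p = 0.00476). The metal-binding protein gene Mt2 rose by 1.42 ± 0.33, the mTOR inhibitor gene Ddit4 by 1.22 ± 0.25, the lipid phosphatase gene Lpin1 by 1.15 ± 0.08 and the lipase inhibitor gene Angptl4 by 1.05 ± 0.14. Igfbp1, whose product binds insulin-like growth factors, rose by 1.04 ± 0.10 (adjusted p = 0.00464), and the glucocorticoid receptor targets Tsc22d3 and Fkbp5 rose by 0.76 ± 0.12 and 0.47 ± 0.12. Amino acid catabolism and gluconeogenesis shared this direction, with the alanine aminotransferase gene Gpt at 1.45 ± 0.26, the proline oxidase gene Prodh at 1.17 ± 0.08, the serine dehydratase gene Sds at 0.95 ± 0.06 and the glucose-6-phosphatase gene G6pc at 0.88 ± 0.23. The gluconeogenic fructose-bisphosphatase gene Fbp1 went the other way and fell to -1.13 ± 0.43 (adjusted p = 0.0122).

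Of 25 glucocorticoid-responsive genes measured in the pools of 3 (median 0.73), 18 were higher and 2 lower when adjusted over the list alone, against 0 when adjusted over all genes in that fit. In the fit of all 3 pairs, adjusted over all genes, 18 rose and 2 fell. The camera test of this list gave an adjusted p of 4.00e-08 with a preset correlation of 0.01, and adjusted p = 0.844 with an estimated correlation. The 21 genes of gluconeogenesis and amino acid catabolism had a median of 0.44 in the pools of 3, where 11 were higher and 2 lower when adjusted over the list alone. Their camera adjusted p of 0.000102 likewise became adjusted p = 0.844 with an estimated correlation, as did that of each of the 12 lists that passed camera in the pools of 3. None of these camera calls held with an estimated correlation. That setting of camera put all 27 lists at adjusted p-values of 0.844 to 0.940. For the 2 lists above, the estimates of -0.04 and -0.03 lay below the preset 0.01, so a larger correlation did not remove their calls. For the other lists that passed, the estimates lay above the preset, from 0.26 (fatty acid and triglyceride synthesis) to 0.82 (B lineage). Their camera p-values at the preset correlation may therefore be too small. With 2 pool pairs the estimate rests on few values and the setting can hardly pass any list, so it decides nothing about the calls.

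Genes of lipid synthesis fell. In fatty acid and triglyceride synthesis, the acetyl-CoA carboxylase gene Acacb fell to -1.51 ± 0.29 (adjusted p = 0.00499), the desaturase gene Scd1 to -1.33 ± 0.15, the lipid-droplet enzyme gene Pnpla3 to -1.28 ± 0.31, the elongase gene Elovl6 to -1.18 ± 0.37 and, chosen after its value was seen, the fatty acid synthase gene Fasn to -0.87 ± 0.15. In cholesterol synthesis, the sterol sensor gene Insig1 fell to -1.03 ± 0.35, the decarboxylase gene Mvd to -0.90 ± 0.29 and the last-step reductase gene Dhcr7 to -0.70 ± 0.22 (adjusted p = 0.0101). Of the 22 fatty acid genes (median -0.45 in the pools of 3), 14 were lower and 1 higher when adjusted over the list alone, and 16 fell and 1 rose in the fit of all 3 pairs adjusted over all genes. Of the 25 cholesterol genes (median -0.42), 19 were lower and 0 higher when adjusted over the list alone, and 18 fell and 0 rose over all genes. Camera adjusted p-values were 6.24e-08 and 6.01e-08, and adjusted p = 0.844 with an estimated correlation for both.

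Fetal liver makes blood at this stage, and genes of the B lineage and of granulocytes fell in it. Among B-lineage genes that fell were the transcriptional coactivator gene Pou2af1 at -1.46 ± 0.48, the immunoglobulin heavy chain gene Ighm at -1.37 ± 0.39, the surrogate light chain gene Vpreb3 at -1.35 ± 0.37 and the lymphoid transcription factor gene Lef1 at -1.29 ± 0.25 (adjusted p = 0.00499). Granulocyte genes fell as well, with lysozyme Lyz2 at -1.10 ± 0.14, lactoferrin Ltf at -1.03 ± 0.15, the chemokine receptor gene Cxcr2 at -0.91 ± 0.23 and the eosinophil peroxidase gene Epx at -1.29 ± 0.56. Of 22 B-lineage genes (median -0.77 in the pools of 3), 16 were lower and 0 higher when adjusted over the list alone, and 16 fell over all genes in the 3-pair fit. Of 28 granulocyte genes (median -0.57), 21 were lower and 0 higher when adjusted over the list alone, and 22 fell over all genes. Camera gave 1.85e-09 for B-lineage and 3.82e-12 for granulocyte genes, and adjusted p = 0.844 with an estimated correlation for both. Erythroid genes had a median of 0.09 over 32 genes (camera adjusted p = 0.405), with 1 higher and 1 lower when adjusted over the list alone, although the carbonic anhydrase gene Car1, the embryonic globin gene Hba-x and the heme enzyme gene Fech rose by 1.82 ± 0.45, 0.98 ± 0.65 and 0.63 ± 0.28. Cell cycle genes had a median of 0.02 over 38 genes (camera adjusted p = 0.651), with 0 past the threshold in either direction when adjusted over the list alone. The thymidine kinase gene Tk1 and the mitotic cyclin gene Ccnb1 rose by 0.44 ± 0.12 and 0.41 ± 0.23 in the 3-pair fit, and the replication genes Top2a and Rrm2 had -0.27 ± 0.16 and 0.22 ± 0.24 (adjusted p = 0.0508 and 0.151).

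Kupffer cell and monocyte genes had a median of -0.16 in the pools of 3, with 8 lower and 2 higher when adjusted over the list alone (camera adjusted p = 0.00145, and adjusted p = 0.844 with an estimated correlation). In this list the lectin gene Clec4f fell to -1.05 ± 0.55, the antigen-presentation gene Cd74 to -0.80 ± 0.25 and the monocyte receptor gene Ccr2 to -0.68 ± 0.17. Endothelial genes had a median of -0.18 (camera adjusted p = 0.000855, and adjusted p = 0.844 with an estimated correlation), with 0 past the threshold when adjusted over the list alone. The vessel regulator gene Sox18 fell to -0.34 ± 0.09, the sinusoid genes Clec4g and Gpr182 to -0.95 ± 0.49 and -0.48 ± 0.30, and the sialomucin gene Emcn had -0.26 ± 0.20 (adjusted p = 0.0822). Without non-uniform spots, other probes of Clec4g and Gpr182 gave -0.19 and 0.02. Megakaryocyte and mast cell genes (median -0.08, camera adjusted p = 0.105) included the basophil protease gene Mcpt8, which fell to -1.17 ± 0.21, and the platelet genes Ppbp, Treml1 and Vwf, which fell to -0.55 ± 0.19, -0.48 ± 0.10 and -0.34 ± 0.09. T and NK cell genes had a median of -0.07 (camera adjusted p = 0.0733), and the cytotoxic granule genes Gzmb, Gzma and Nkg7 and the receptor chain gene Cd3d fell to -0.80 ± 0.34, -0.65 ± 0.42, -0.69 ± 0.10 and -0.48 ± 0.15. Medians and camera adjusted p-values were -0.08 and 0.0873 for stellate, mesenchymal and mesothelial genes, of which the retinol-storing enzyme gene Lrat and the matrix gene Reln fell to -0.96 ± 0.45 and -0.34 ± 0.03, the mesothelial factor gene Wt1 rose by 0.34 ± 0.13 and the collagen gene Col1a2 had -0.17 ± 0.45 (adjusted p = 0.508). For bile duct genes they were -0.11 and 0.0873, and the ductal transcription factor genes Sox9 and Onecut1 and the matrix protein gene Spp1 fell to -0.92 ± 0.33, -0.35 ± 0.14 and -0.77 ± 0.35, while the keratin gene Krt23 had -0.66 ± 0.74 (adjusted p = 0.140).

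Ranked by size in the pools of 3 among genes measured without non-uniform spots, as planned, the 10 lowest genes included 7 interferon-stimulated genes, of which Ifi44, Slfn4, Ifi27l2a and Oas2 fell to -1.88 ± 0.96, -1.79 ± 0.72, -1.65 ± 0.88 and -1.45 ± 0.81, and the chemokine gene Cxcl10 to -1.66 ± 1.13 (adjusted p = 0.0431). Ifit1 at -1.43 ± 1.25 (adjusted p = 0.0789) did not pass, and Irf7 at -1.23 ± 0.85 passed with an adjusted p of 0.0462 only with non-uniform spots kept. The other 3, which also fell, were the epoxygenase gene Cyp2j5 (-1.80 ± 0.93), the little-studied gene Fam47e (-1.55 ± 0.68) and the long noncoding RNA gene Dleu2 (-1.59 ± 0.27). The 10 highest genes, all of which rose, were led by the bile acid sulfotransferase gene Sult2a6 at 3.54 ± 0.67 and its relative Sult2a4 at 1.90 ± 0.37, near-identical genes whose signals may be shared. The organic anion carrier gene Slco4c1 rose by 1.90 ± 0.45, the polymerase II regulator gene Rprd2 by 1.90 ± 0.31, the zinc finger gene Zc3h6 by 1.64 ± 0.30, the arrestin-family gene Arrdc4 by 1.40 ± 0.15 and the dynein chain gene Tcte3 by 1.38 ± 0.03. The histone gene H2bc22, the circadian repressor gene Nr1d2 and the immune checkpoint gene Havcr2 rose by 1.27 ± 0.50, 1.36 ± 0.15 and 1.25 ± 0.43. All 20 genes had the same sign on all 6 fetal arrays because the naming rule required it, so this is no check of their agreement. With non-uniform spots kept the ranking changed. Isg15, Abca8a, Prok1 and Aqp8 took the place of Oas2, Irf7, Fam47e and Dleu2 among the lowest, which left 6 interferon-stimulated genes. Cirbp, Trnp1, Cyp3a25, Abca6, Tat and Akr1c18 entered the highest, where only Sult2a6, Slco4c1, Rprd2 and Sult2a4 stayed. Probes of a gene could disagree. Without non-uniform spots, the 3-pair limma fit read other probes, with -0.12 for Prok1 (adjusted p = 0.131) and 0.85 for Cyp3a25 (adjusted p = 0.174). Of 6 Rprd2 probes, 4 lay between -0.01 and 0.11 in the fetuses, and dimmer probes gave 0.82 for Slco4c1, 0.43 for Arrdc4, -0.50 for Ifi44, -0.09 for Oas2 and -0.05 for Acacb. In the pools of 3 alone none passed, as limma adjusted p-values of the 20 genes ranked as planned lay between 0.0515 and 0.133. In the coordinates of the slide 1 files (mm9), the Ifi44 probe lay on chromosome 3 at 151394035 to 151394094, the Sult2a6 probe on chromosome 7 at 14811313 to 14811372 and the Tat probe on chromosome 8 at 112523207 to 112523266.

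**Figure D1:**
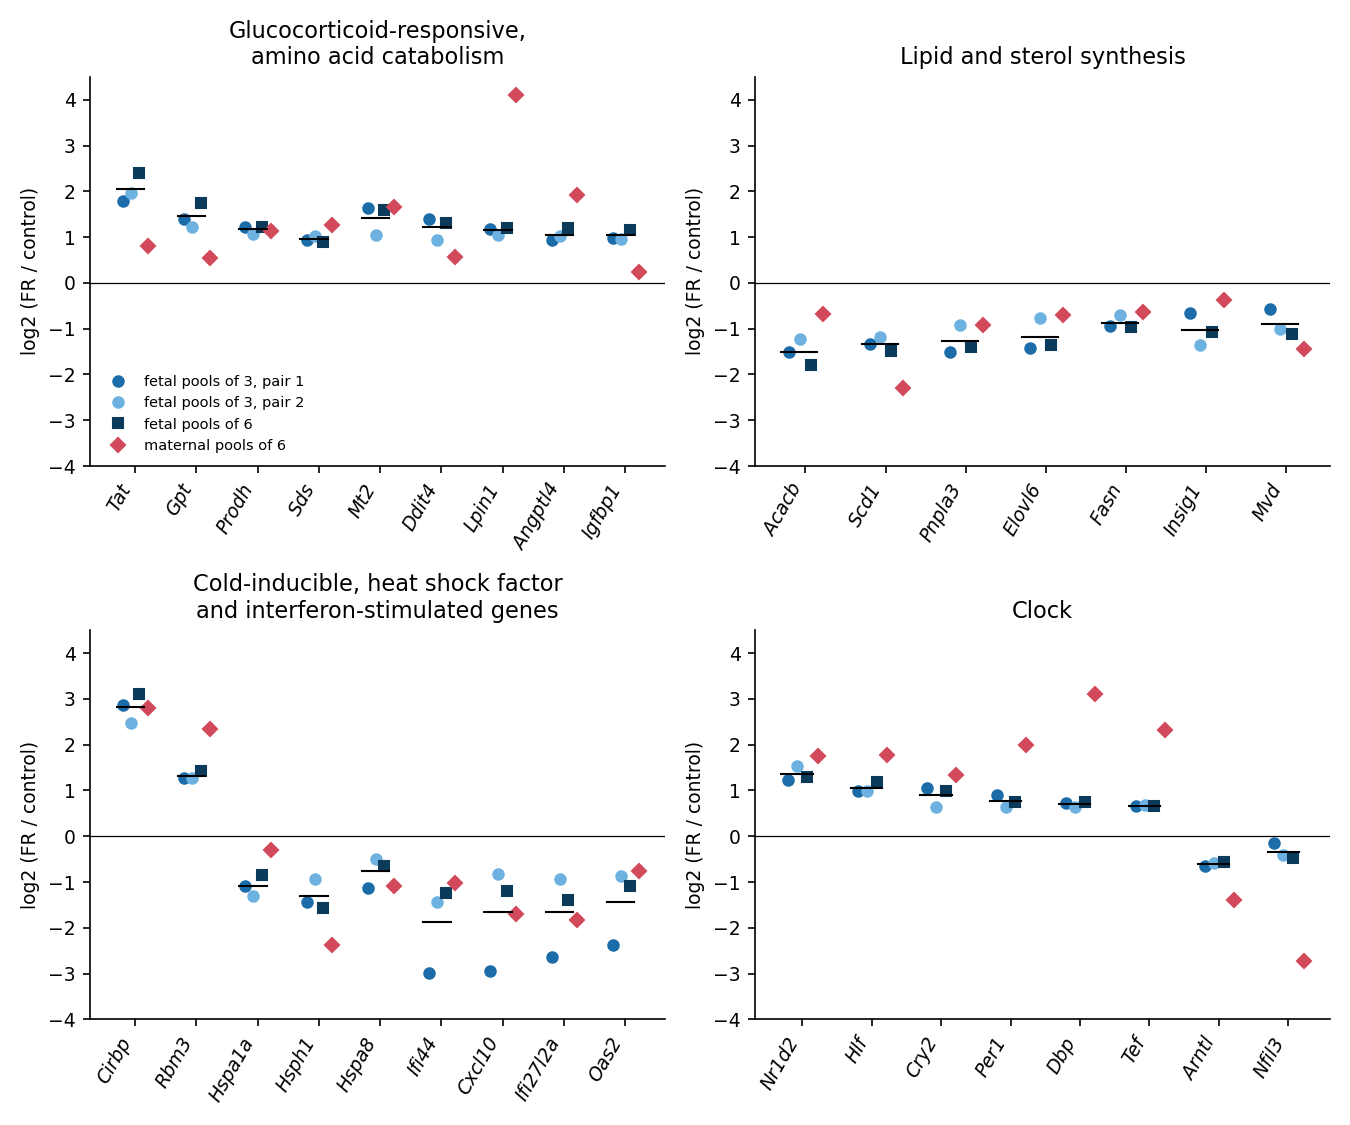
Log2 ratio of FR over control (vertical axis) for genes of 4 groups, in the 2 pairs of fetal pools of 3 (circles), the fetal pools of 6 (squares) and the maternal pools of 6 (diamonds), with the fetal mean as a bar. Tat lies between 1.79 and 2.40 in the fetal pairs, and Ifi44 between -2.98 and -1.23.

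Clock genes, with a median of 0.12 over 20 genes, moved in both directions in fetal liver. The list's activator gene Arntl and its output factor genes Dbp and Tef were chosen after their values were seen. The output factor genes Hlf, Dbp and Tef rose by 1.05 ± 0.11, 0.71 ± 0.05 and 0.67 ± 0.01. The repressor genes Cry2 and Per1 rose by 0.90 ± 0.22 and 0.76 ± 0.12, although a dimmer Cry2 probe gave 0.05. Arntl fell to -0.60 ± 0.04 (adjusted p = 0.00497). In the pools of 3, 7 clock genes were higher and 3 lower when adjusted over the list alone, and 8 rose and 4 fell in the 3-pair fit over all genes. Camera gave an adjusted p of 0.0722, and fry, a rotation test, gave 0.0485, its only list under 0.05. Endoplasmic reticulum chaperone genes had a median of -0.27, with 7 lower and 0 higher when adjusted over the list alone (camera adjusted p = 0.000538, and adjusted p = 0.844 with an estimated correlation). The unfolded-protein regulator gene Xbp1 fell to -0.79 ± 0.21, the cochaperone gene Dnajb9 to -0.57 ± 0.12, the degradation factor gene Edem1 to -0.63 ± 0.26 and the disulfide isomerase gene Pdia6 to -0.56 ± 0.08. In the list of metallothionein, oxidative stress and heat shock genes (median -0.08, camera adjusted p = 0.362), Mt1 rose by 1.18 ± 0.35 while the inducible chaperone genes Hspa1a and Hsph1 fell to -1.08 ± 0.23 and -1.31 ± 0.33.

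In the list of insulin, IGF and leptin signalling, Trib1, whose product steers protein degradation and lipid genes, fell to -0.69 ± 0.22 (adjusted p = 0.0106) and its relative Trib3 rose by 0.79 ± 0.10. The imprinted growth inhibitor gene Grb10 fell to -0.61 ± 0.24, and the insulin receptor substrate gene Irs1 to -0.81 ± 0.23 on its brightest probe, against -0.08 on the probe left without non-uniform spots. The leptin receptor gene Lepr had -0.28 ± 0.40 (adjusted p = 0.236), Igf1 -0.18 ± 0.16 (adjusted p = 0.135) and Igf2 0.16 ± 0.26 (adjusted p = 0.326). The list's median was -0.15 in the pools of 3, with 2 higher and 9 lower when adjusted over the list alone (camera adjusted p = 0.0722). Acute phase and plasma protein genes (median -0.28, camera adjusted p = 0.0254, and adjusted p = 0.844 with an estimated correlation) held opposite changes, since the protease inhibitor gene A2m fell to -1.75 ± 0.16, the serum amyloid gene Saa3 to -1.27 ± 0.25 and the fibrinogen gene Fgg to -0.73 ± 0.30, while the iron hormone gene Hamp rose by 1.66 ± 0.81. Xenobiotic metabolism had a median of 0.20 (camera adjusted p = 0.0366, and adjusted p = 0.844 with an estimated correlation), with 9 higher and 1 lower when adjusted over the list alone. In it the quinone reductase gene Nqo1 rose by 0.67 ± 0.16 and the drug-metabolizing gene Cyp3a11 by 1.08 ± 0.78 (adjusted p = 0.0497), its relative Cyp3a41a had a mean fold of 2.14 (adjusted p = 0.0619), and Cyp2c29 fell to -0.78 ± 0.36. Cyp3a genes are alike in sequence and may share signal. Fatty acid oxidation and ketogenesis had a median of -0.11 (camera adjusted p = 0.526), with 7 higher and 6 lower when adjusted over the list alone, and the fatty acid hydroxylase gene Cyp4a14 had 1.18 ± 0.94 (adjusted p = 0.0626).

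Bile acid and sterol transport had a median of -0.05 (camera adjusted p = 0.549). Its bile acid hydroxylase gene Cyp8b1, the conjugating enzyme gene Baat and the cholesterol exporter gene Abca1 fell to -1.19 ± 0.17, -0.92 ± 0.45 and -0.43 ± 0.18, the sterol exporter gene Abcg5 rose by 0.66 ± 0.41, and Cyp7a1, which starts bile acid synthesis, had -0.24 ± 0.27 (adjusted p = 0.161). The amino acid and integrated stress response list had a median of 0.07 (camera adjusted p = 0.616). In it the stress regulator gene Nupr1 fell to -1.27 ± 0.15 and the cysteine-making enzyme gene Cth rose by 0.91 ± 0.34. Mature hepatocyte genes had a median of 0.14 (camera adjusted p = 0.113), where albumin Alb fell to -0.45 ± 0.15. The gluconeogenic gene Pck1 gave no value that passed the filters. Fetal hepatoblast genes had a median of 0.04 (camera adjusted p = 0.879), with alpha-fetoprotein Afp at -0.35 ± 0.22 (adjusted p = 0.0446), the plasma protein gene Ahsg and the imprinted gene Peg3, which fell to -0.31 ± 0.16 and -0.45 ± 0.22, and the RNA-binding regulator gene Lin28b, which rose by 0.67 ± 0.15. Pancreas and gut genes, listed to find tissue carried over at dissection, had a median of 0.43 (camera adjusted p = 0.00574, and adjusted p = 0.844 with an estimated correlation). The pancreatic elastase gene Cela3b differed between pairs, at -0.35 and 1.53 in the pools of 3 and 1.45 in the pools of 6. Its microvillus gene Vil1 fell to -1.04 ± 0.10, and the gut lectin gene Lgals2 and the elastase gene Cela1 rose by 1.03 ± 0.48 and 0.57 ± 0.17. Muscle, fat and plasma genes had a median of 0.02 (camera adjusted p = 0.929), and the muscle myosin gene Myh8 had 1.64 in the pools of 6 alone, with -0.73 and 0.19 in the pools of 3. The fat cell gene Fabp4 fell to -0.90 ± 0.15, and the muscle genes Acta1 and Myh3 had 0.16 ± 0.78 and 0.42 ± 0.36 (adjusted p = 0.726 and 0.0868).

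**Figure D2:**
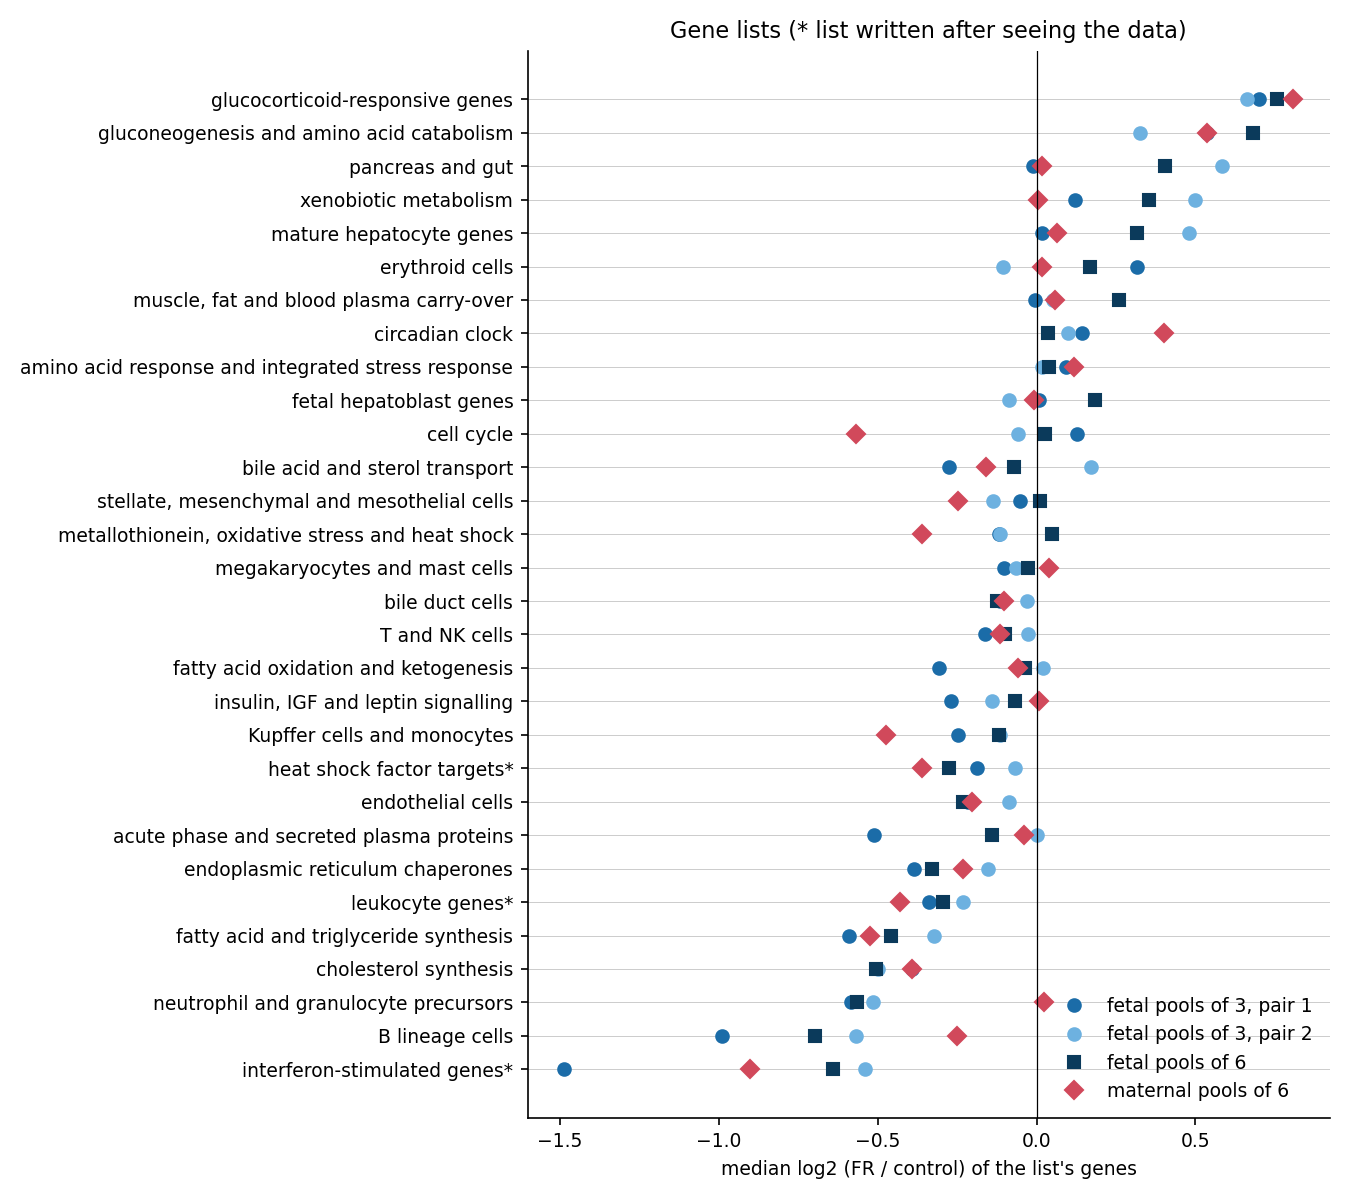
Median log2 ratio of FR over control (horizontal axis) of the 27 planned gene lists and of 3 lists written after the data were seen (asterisk), in each fetal pool pair and in the mothers, with non-uniform spots kept and ordered by the fetal mean. The cold-inducible and chaperonin lists are not drawn. Of those drawn, glucocorticoid-responsive genes lie highest, with a maternal median of 0.81, and interferon-stimulated genes lowest, with a maternal median of -0.90.

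Counted over all genes, limma on the 2 pairs of pools of 3 put 0 of 21349 genes past an adjusted p of 0.05, with a smallest adjusted p of 0.0515 shared by 52 genes. At an unadjusted p under 0.05 there were 6177 genes, against 1067 expected by chance, and 3609 genes had an adjusted p under 0.10 (1661 higher, 1948 lower). The 0 depended on the setting, as 957 genes passed with a normexp offset of 10 and 2835 with scaling between arrays. With all 3 pool pairs, 1337 genes rose and 1831 fell of 16231 tested, and 2399 rose and 3005 fell of 21097 with non-uniform spots kept. That count rested on treating the pools of 6 as another replicate. It was 274 with the slide as a random block at a set correlation of 0.5, 0 without the pools of 6, and 1839 without the first pair of pools of 3.

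The second question was whether the pools of 6 on slide 1 repeated the values of the pools of 3 on slide 2. Sulfotransferase Sult2a6 had 2.86 and 4.19 in the pools of 3 and 3.58 in the pools of 6, and A2m had -1.87, -1.57 and -1.81. Interferon-stimulated genes varied more, as Cxcl10 had -2.94, -0.83 and -1.21. Across 16231 genes, the mean of the pools of 3 and the pools of 6 correlated with Pearson r = 0.848 and Spearman rho = 0.757. The 2 pairs of pools of 3 correlated with r = 0.740. Genes are not independent replicates, so no p-value belongs to these correlations. With non-uniform spots left out, 1776 of the genes with a limma adjusted p under 0.10 in the pools of 3 had a value in the pools of 6. Of these, 96.8% had the same sign in the pools of 6, against 74.9% of all genes with such a value. The pools of 6 may share mothers or RNA with the pools of 3, so this agreement is not an independent repeat. Spots marked as non-uniform gave r = 0.899 over 7707 genes, and spots not so marked gave 0.847 over 13642. The marked spots were brighter (median log2 intensity 11.3 against 7.67), so the higher r does not show that they are as reliable.

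**Figure D3:**
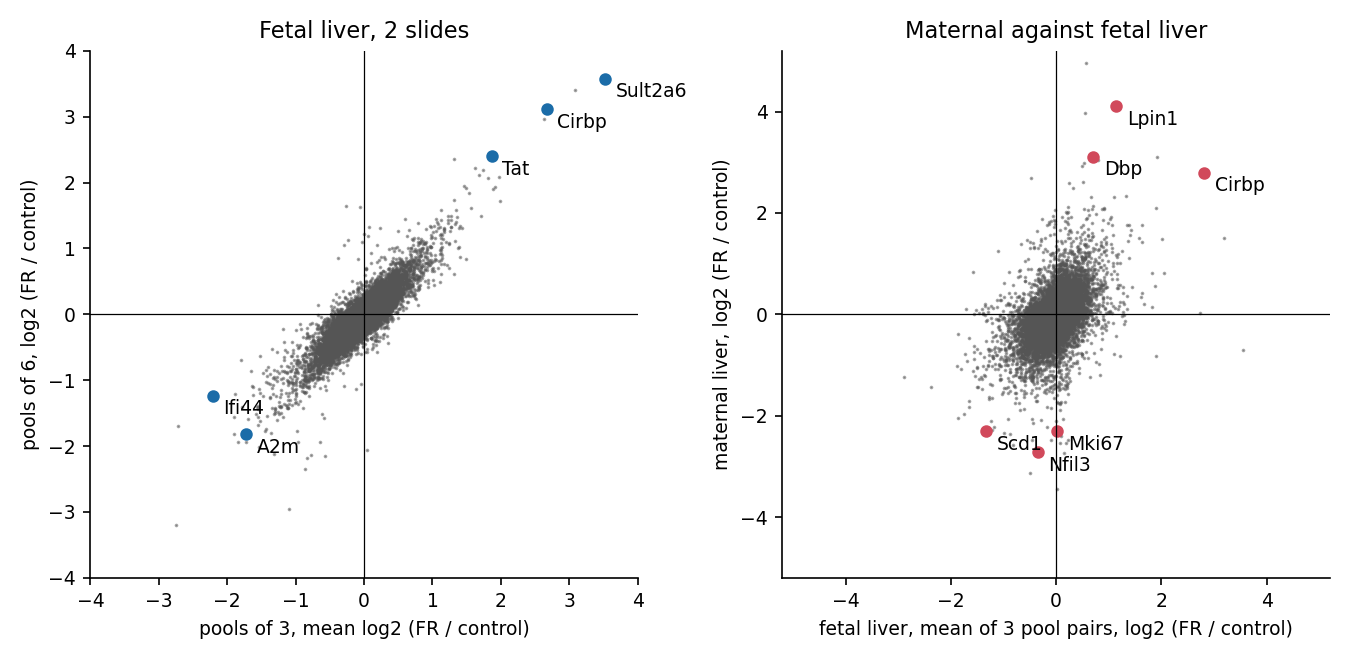
Each point is a gene. The left panel plots the log2 ratio in the fetal pools of 6 (vertical) against the mean of the pools of 3 (horizontal), and the right panel plots the maternal log2 ratio (vertical) against the fetal mean of 3 pool pairs (horizontal). With non-uniform spots kept, as plotted, r is 0.871 in the left panel and 0.491 in the right panel. Each panel sets a mean of several pool pairs against 1 pair, and single fetal pairs without those spots correlate at 0.740 to 0.817.

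The third comparison asked how maternal liver responded to the same diet. Clock genes had some of the largest ratios, as the clock repressor gene Ciart had 2.99, the clock-controlled protease gene Usp2 2.92 and the repressor genes Per1, Nr1d2 and Nfil3 1.99, 1.76 and -2.52. With non-uniform spots kept, the output factor genes Dbp and Tef had 3.11 and 2.31. The clock list had a median of 0.30 over 16 genes, above all 10000 random lists of equal intensity, with 5 genes over 2-fold higher and 2 over 2-fold lower. Glucocorticoid-responsive genes had a median of 0.39, also above all random lists. Sult1e1, which inactivates estrogens, had 2.60, and with non-uniform spots kept Lpin1 was 17.2-fold higher, the transcription factor gene Cebpd had 2.14 and Angptl4 1.91. Gluconeogenesis and amino acid catabolism had a median of 0.54 over 21 genes with non-uniform spots kept, above all random lists, and the coactivator gene Ppargc1a and the amino acid carrier gene Slc38a2 had 1.24 and 1.13. The kinase gene Map3k6 and the fasting regulator gene Cebpb had 1.51 and 1.69. The genes read from non-uniform spots were chosen after their values were seen.

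Proliferation genes had the lowest maternal median of the 27 planned lists. The cell cycle list had a median of -0.60 over 37 genes, below all random lists, with 12 genes over 2-fold lower, led by the anaphase activator gene Cdc20 at -2.54, the proliferation marker gene Mki67 at -2.31 and the survivin gene Birc5 at -1.84. Cholesterol synthesis had a median of -0.37 (percentile 0.0300), with Mvd at -1.44, the farnesyl synthase gene Fdps at -1.37 and the sterol dehydrogenase gene Nsdhl at -1.32. The brightest probes of Fdps and Nsdhl, left out as non-uniform, gave -0.39 and -0.23. The sterol desaturase gene Sc5d had -2.37 from its unmarked probe and -1.14 from its brightest. Fatty acid and triglyceride synthesis had a median of -0.22 (percentile 0.800), the sugar-sensing regulator gene Mlxipl had -0.98 and Pnpla3 -0.93, and with non-uniform spots kept Scd1 had -2.30. Kupffer cell and monocyte genes had a median of -0.54, below all random lists, with the macrophage gene Aif1 at -1.08, and stellate and mesenchymal genes -0.23 (percentile 0.790), with the collagen genes Col3a1 and Col1a1 at -2.11 and -1.46. The choline kinase gene Chka had -3.13, the chaperone gene Hsph1 -2.38, the hydroxyacid oxidase gene Hao2 -2.35, the carbonic anhydrase gene Car3 -2.32 and the interferon-induced GTPase gene Gbp6 -2.28. On the higher side, the adenosine receptor gene Adora1 had 2.70, the lipin gene Lpin2 2.60, the kinase gene Map2k6 2.49, the adhesion gene Vsig2 2.11, Rprd2 2.09, the cholesterol exporter gene Npc1 2.09 and the epoxygenase gene Cyp2j9 2.07. The brightest Adora1 probe, left out as non-uniform, gave 1.59 and the dimmest 0.25, 4 of 6 Rprd2 probes lay between -0.05 and 0.09, and a dimmer Map2k6 probe gave 0.61. Other dimmer probes gave -1.18 for Mki67, -0.53 for Col1a1, -2.57 to -1.30 for Chka and 1.51 for Usp2. The leptin receptor gene Lepr had 1.45, the IGF carrier gene Igfals -1.14 and the stress response gene Chac1 1.76, and Trib1, readable only from non-uniform spots, had 0.75.

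Other maternal list medians outside the middle 95% of random lists were -0.30 for endoplasmic reticulum chaperones, -0.58 for acute phase genes, -0.25 for B-lineage genes, -0.12 for T and NK cells, -0.21 for bile acid and sterol transport and 0.12 for the amino acid and integrated stress response. Within the middle 95% were fetal hepatoblast (0.01), fatty acid oxidation (-0.19), insulin, IGF and leptin (0.07), xenobiotic (0.08) and metallothionein, oxidative stress and heat shock genes (-0.17). Also within it were erythroid (0.05), granulocyte (0.02), megakaryocyte and mast cell (0.03), endothelial (-0.07), bile duct (-0.08), pancreas and gut (0.02) and muscle, fat and plasma genes (0.06). No mature hepatocyte gene was measured without non-uniform spots, and with them the list's median was 0.06. Which lists lay outside depended on those spots. With them kept, acute phase genes (-0.04 over 26 genes, against 7 genes without them) and bile acid and sterol transport (-0.16) lay within the middle 95%. Metallothionein, oxidative stress and heat shock genes (-0.36 over 21 genes, against 11) and endothelial genes (-0.20) then lay below it. On both maternal arrays, 131 genes were over 2-fold higher and 149 over 2-fold lower of 16242 measured, and 196 and 229 of 19507 with non-uniform spots kept. The arrays of both dye orientations correlated with r = 0.779 across genes. Keeping non-uniform spots changed the probe read for 1833 genes, and the Igf1 value went from 1.15 to -0.50 between probes.

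The fourth comparison set the maternal response against the fetal one. Lpin1, Nr1d2 and Scd1 had the same sign in both, as Lpin1 was 17.2-fold higher in the mothers and rose by 1.15 ± 0.08 in the fetuses, Nr1d2 had 1.76 and rose by 1.36 ± 0.15, and Scd1 had -2.30 and fell to -1.33 ± 0.15. Without non-uniform spots, a few genes that passed in all 3 fetal pairs and were over 1.5-fold on both maternal arrays had opposite signs. For those named next limma on the difference passed, but only with the fetal spread taken for the mothers, so their maternal values are descriptive. The adipogenesis-related gene Fam13a had 1.47 in the mothers and -0.55 in the fetuses (adjusted p of the difference = 0.0130), the lipid-droplet gene Plin4 1.32 and -0.43, and the clotting factor gene Vwf 1.18 and -0.37. The channel regulator gene Unc79 had 1.30 and -0.22, and the glycosyltransferase gene Tmtc2 0.90 and -0.33. In the other direction, the mitochondrial carrier gene Slc25a30 had -1.45 in the mothers and 0.21 in the fetuses, the stress hormone gene Gdf15 -1.01 and 0.27, the guanylate cyclase gene Gucy2c -0.70 and -1.31 on the maternal arrays and 0.19 in the fetuses, and the adhesion gene Cdcp1 -0.91 and 0.22.

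Across 15730 genes, maternal ratios and the fetal pools of 3 correlated with r = 0.487 (Spearman rho = 0.454). Within slide 1, where the mothers met the fetal pools of 6, r was 0.502. With the pools of 3, no fetal gene passed over all genes, so the planned count of opposite genes was 0. Of 2982 genes called in all 3 fetal pairs and measured in the mothers, 330 were over 1.5-fold the same way on both maternal arrays and 17 the opposite way. Independent lists would share 26.5 genes higher in both against 161 found, and 37.1 lower in both against 169 found. For the 2 opposite combinations independent lists would give 26.9 and 36.6 genes, against 6 and 11 found. As far as the design text says, the fetuses came from the profiled mothers, so mothers and fetuses are not independent samples of animals. The difference itself, tested with limma on the mothers and the pools of 3, passed for 0 of 15730 genes (smallest adjusted p = 0.0582, 2496 genes at an unadjusted p under 0.05), and for 209 of 13554 with all 3 fetal pairs, 106 higher in the mothers and 103 lower. The lone maternal pool pair was assumed to vary like the fetal ones.

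The last comparison described control liver of mothers against control liver of fetuses on slide 1, as a check of the labels. Afp and Igf2, which fetal liver makes, had log2 ratios of mothers over fetuses of -9.24 and -9.16. The eosinophil gene Ear6 had -4.88 and the pre-B cell gene Vpreb1 -4.46. The blood progenitor gene Myb, not well above background in the mothers, was at least 19.2-fold higher in the fetuses. The X-inactivation gene Xist had a log2 level of 13.0 in the mothers and was near background in the fetuses (above it on 1 of 2 arrays), so no difference is given. The carrier gene Slc22a30 and Saa1 were higher in the mothers by 6.03 and 5.79, and the sulfotransferase gene Sult3a2, not well above background in the fetuses, by at least 57.9-fold. Of 17500 genes, 178 were over 4-fold higher in the mothers in both dyes and 208 over 4-fold higher in the fetuses. With non-uniform spots kept, 1318 genes differed over 4-fold.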

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

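The test of the maternal minus fetal difference was planned, and the reading of the spike-in spots was chosen only after the data were seen. With all 3 fetal pool pairs, 209 genes passed limma on the maternal minus fetal difference. This test took the fetal spread for the lone maternal pair, whose own spread was not measured, so it does not show that the tissues differ beyond the variation between maternal pools. Those with an official symbol that passed in all 3 fetal pairs, were over 1.5-fold on both maternal arrays and had opposite signs in the 2 tissues were Fam13a, with a maternal minus fetal log2 ratio of 2.02, Plin4 (1.75), Vwf (1.55), Unc79 (1.51), Tmtc2 (1.23), the autophagy gene Atg16l2 (1.18), the transcription cofactor gene Lmo4 (1.15) and the choline transporter gene Flvcr2 (0.84). On the other side were Cdcp1 (-1.14), Gucy2c (-1.19), Gdf15 (-1.29) and Slc25a30 (-1.66). Mothers and the pools of 3 sat on different slides, and with the pools of 6 alone, on the slide of the mothers, no test was possible because 1 pool pair was left on each side.

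The other signal stood in spots that no comparison used. The E1A spike-in probes (10 probes, 320 spots per array), which detect RNA added at labelling, had a median Cy5 signal of 9756 on slide 1 and 8838 on slide 2 (maternal arrays 11476 and 13687, fetal pools of 6 6995 and 8036, pools of 3 7908 to 9601), above negative control medians of 49.9 and 71.5. The amounts added are not stated in the labels.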

How the results depend on the processing

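The settings that kept non-uniform spots, used median signals, took the slide as a block or adjusted over genes measured in both comparisons were chosen only after the results were seen, and the others were planned. Unless a cause is given, the cause was not tested.

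Named fetal genes kept direction and side of the threshold in 1511 gene and setting combinations. In 194 they no longer passed (104 without the pools of 6, 54 with scaling between arrays), in 37 they newly passed and in 7 they moved. For maternal genes, 806 combinations were kept and 311 moved. Igf1 went to -0.50 in the mothers with non-uniform spots kept, as another probe was read.

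Fetal genes in the pools of 3, 0 in limma as planned with 6177 at an unadjusted p under 0.05, numbered 957 with offset 10, 2359 without loess, 2835 with scaling, 815 without the dim filter, 61 with both channels above background, 908 with trend and robust priors and 3609 at an adjusted p under 0.10. They numbered 6028 when 4 arrays entered with the pool pair as a random block and with a dye term, and 0 with the pairing dropped (unpaired single channels, 2 against 2). They were 3168 with all 3 pairs, and between 575 and 1410 with 1 pair left, by 1.5-fold on both arrays with no test. They were 0 in the other settings (processed signals, deposited table, mean of probes, median signals, non-uniform spots kept, and 1.5-fold as well). The count of all 3 pairs became 5404 with non-uniform spots kept, where more genes were tested, 4823 at an adjusted p under 0.10, 586 at 1.5-fold or more and 274 with the slide as a block. Leaving out 1 pair gave 0 (without the pools of 6) to 2673, and 1839 without the first pair of pools of 3. The share of higher genes went from 42.2% to 33.6% without loess and to 50% with the slide as a block.

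Maternal genes over 2-fold, 280 as planned, numbered 440 with offset 10, 849 with processed signals and 849 in the deposited table, 114 without loess, 425 with non-uniform spots kept, 544 on the array with FR in Cy5 alone (172 higher, 372 lower), 518 with FR in Cy3 alone (313 higher, 205 lower, so the balance of directions reversed with the dye), 919 at 1.5-fold and 691 by limma with the fetal spread. Levels over 4-fold, 386 as planned, numbered 1318 with non-uniform spots kept, 1906 at 2-fold, 996 against the pools of 3 and 1878 with processed signals scaled by the 75th percentile.

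The difference of mothers and fetuses, 0 by limma as planned with 2496 at an unadjusted p under 0.05, was 185 with offset 10, 435 with processed signals or the deposited table, 157 without loess, 1215 with scaling, 81 without the dim filter, 52 with the mean of probes, 14 with trend and robust priors and 287 at an adjusted p under 0.10. It was 209 with all 3 pairs, 792 with non-uniform spots kept as well, 117 with the pools of 6 only and 192 to 240 without 1 pair of pools of 3, the last 2 with no test. Opposite genes, 0 as planned, were 15 when adjusted over genes measured in both, 9 with offset 10, 4 without loess, 22 with scaling, 6 without the dim filter, 1 with both channels above background, 17 with all 3 pairs, 59 with non-uniform spots as well, 3 with the pools of 6 only and 7 to 15 without 1 pair.

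The mother to fetus correlation lay between 0.429 and 0.479 without 1 pair of pools of 3, was 0.451 with FR in Cy3 alone and otherwise ranged from 0.457 to 0.520. The correlation of pools of 6 and pools of 3 was 0.740 without loess. Fetal lists past the threshold, 12 by camera as planned, were 0 with an estimated correlation and 1 by fry (the clock list, which is not among the 12), and 11 to 15 in other settings that camera could fit. An estimated correlation can hardly pass any list with 2 pool pairs, so that 0 does not decide about the 12. With 1 pair left camera could not be fitted, and 17 to 18 lists (leaving out 1 pair) or 11 (pools of 6 only) lay outside the middle 95% of random lists, as did 15 by that rule in both pairs of pools of 3. Maternal lists outside the middle 95% ranged from 13 to 15, and keeping non-uniform spots changed which lists these were. The number of arrays and the signal over background limit the precision of all these counts.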

Other observations

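The 5 lists in this part, the tests of the pool pairs, leukocytes, cold-inducible probes and dye orientation were chosen only after the results were seen. Those of chaperonins, intensity and the exchange of diets were written before their results were seen.

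Interferon-stimulated genes were lower in FR livers. Over 50 genes, the fetal median of 3 pool pairs was -0.88, 35 genes fell and 0 rose by limma over all genes (45 and 0 when adjusted over the list alone), and the maternal median was -0.90, below all random lists. The antiviral gene Isg15, chosen after its value was seen, fell to -2.38 ± 1.31 in the fetuses (adjusted p = 0.0252). The fall was not confined to 1 pool pair, as the pair medians were -1.49, -0.54 and -0.64. The highest of them, -0.54, lay below all random lists. The fall was largest in the first pair of pools of 3. The list was written after these pairs were seen, and the pools may share mothers or RNA. The percentiles are therefore no independent check, and how far 1 pair drove the size of the fall stays open. That FR liver held fewer leukocytes stays open: 30 leukocyte genes had a median of -0.29 in the fetuses and -0.43 in the mothers, with 21 lower and 1 higher in the fetuses over all genes (21 and 1 when adjusted over the list alone). They ran from Cd52 and Ptprc, the lowest, at -0.84 ± 0.24 and -0.82 ± 0.17, to Rgs1 at 0.95 ± 0.32, named after their values were seen. The gap between the lists, -0.60 ± 0.47, was less than 2 SD from 0. A weaker interferon response under FR may add to it and remains untested.

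Cold-inducible genes were higher, and heat shock factor targets were lower in the mothers and in 2 of the 3 fetal pool pairs. Cirbp, whose product binds RNA after cooling, rose by 2.82 ± 0.32 in the fetuses (adjusted p = 0.00395) and had 2.79 in the mothers, and Rbm3, of the same family, rose by 1.32 ± 0.09 and had 2.34 in the mothers. The 2 genes had a fetal median of 2.07 and a maternal one of 2.57. Over 27 heat shock factor targets the fetal median was -0.16, with 12 lower and 2 higher over all genes (13 and 3 when adjusted over the list alone), and the maternal median was -0.36 (outside the middle 95% of random lists). The fetal pair medians were -0.19, -0.07 and -0.28, at percentiles 0.955, 6.92 and 0, so the second pair lay within the middle 95%. The Cirbp probe lies on chromosome 10 at 79634274 to 79634333 and the Rbm3 probe on chromosome X at 7719656 to 7719715 (mm9).

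A general fall of chaperone genes was argued against as the source of the lower heat shock factor targets, because the 16 chaperonin genes had a fetal median of 0.10 and a maternal one of 0.11, and the heat shock factor targets lay -0.29 ± 0.08 from them over the 3 pairs. Endoplasmic reticulum chaperones were lower as well, with medians of -0.27 in the fetal pools of 3 and -0.30 in the mothers, so a fall that heat shock factor targets share with them stays open. Whether single probes gave the cold-inducible rise cannot be told apart from a change of the genes, since Cirbp had 1 probe and the second Rbm3 probe had -0.25 in the fetuses and -0.10 in the mothers. A lower body temperature of FR mothers, and with it of their fetuses, is a candidate explanation, but temperatures are not in the files. Fetuses of both diets were placed on ice-cold saline, per the labels, which name no such step for the mothers.

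Maternal and fetal ratios correlated across genes with r = 0.487, although the mothers and the pools of 3 shared no array or slide. As far as the design text says, however, the fetuses came from the profiled mothers, so the tissues are not independent samples of animals. The correlation cannot separate the diet from other differences between the control and FR mothers. A dye bias common to the slides was argued against as the whole source, because maternal arrays and those of the pools of 3 of opposite dye orientation still correlated over the same genes, with r between 0.313 and 0.409. Over probes well above background on all arrays, with the pools of 6 included, r was 0.317 to 0.436 for opposite and 0.423 to 0.549 for equal orientation. A trend with intensity left by the normalization was argued against as well, because r within each of 10 groups of genes by intensity lay between 0.362 and 0.551. Genes are not independent replicates. A response to FR that mothers and fetuses share may explain the correlation, as may a difference between the diets in handling, in the hour of the last meal or in the order of sampling, none of which the labels give.

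When the diets were exchanged within the 3 fetal pool pairs, 1 of the 4 assignments, the real one, gave as many as 3168 genes, and the highest of the others was 0. The 4 assignments are too few for a share under 0.05. The pairs correlated with each other, so turning any 1 of them shrinks the mean and widens the spread, whatever made them agree. The contrast of 3168 and 0 therefore does not tell the diet from another source of that agreement.

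In the mothers, the G protein regulator gene Rgs16 had 4.96 and the translation repressor gene Eif4ebp3 3.97 with non-uniform spots kept, both chosen after their values were seen.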
